A study of Mus musculus with 6 samples.

How the data were processed

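The series holds 6 samples of total RNA from splenic CD4+ T cells of the mouse, cultured in RPMI medium with 10% serum and stimulated with antibodies against CD3 and CD28 at 1 µg/ml for 12 hours, per the labels' protocols. The groups are ConCM, PlGFCM and IL6_ConCM with 2 replicate samples each, taken from the treatment that the labels give for every sample. RNA was labelled for an Affymetrix whole-transcript array. The deposited table gives a log2 level per probe set for each array, which the authors made with Transcriptome Analysis Console, per the submitters' processing notes. Its version, the background correction, the normalization method and the genome build are not given in the sources used here, so no coordinates are printed. The log2 scale was read from the values, which have the same range and nearly the same distribution on all 6 arrays, and no further normalization was applied. Arrays give no read depth, so the number of arrays limits the precision.

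The table holds 41345 probe sets. The platform annotation lists 25335 of them, 23521 with 1 gene symbol and 1814 with several, and the other 16010 are unnamed here. Gene IDs of 23328 of the probe sets with 1 symbol were found in the RefSeq gene table, which changed 0 symbols. Probe sets with several symbols were left out, and for genes with more than 1 probe set the brightest over the 6 arrays was used, which gave 22180 genes with no filter on low levels. Probe sets of gene families such as Ly6, Ifit, Ctla2 and the olfactory receptors can bind related transcripts, so their gene assignment is uncertain.

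Differences were tested with limma version 3.58.1 in R 4.3.3, by lmFit and eBayes with an intensity trend on all 6 arrays, with 3 residual degrees of freedom and a median prior of 8.14. The 3 contrasts were PlGFCM minus ConCM, IL6_ConCM minus ConCM and PlGFCM minus IL6_ConCM. A gene was said to rise, fall or change where its Benjamini-Hochberg adjusted p over all 22180 genes was under 0.05. The labels do not say whether replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. An exact permutation test of 2 against 2 arrays cannot give a two-sided p below 1 in 3. The share of genes whose groups do not overlap was 38.2%, 34.1% and 30.1% in the 3 comparisons, where chance gives 1 in 3.

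The tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes, per comparison, up to 10 named genes per direction with the largest log2 change among those that passed and whose groups do not overlap, filled to 5 by smallest p where fewer passed, and for each gene list up to 4 members with the smallest p. It adds Pgf, Flt1, Nrp1, Il6, Il6ra, Il6st, Socs3, Stat3, Il17a, Il17f, Il21, Foxp3, Tbx21, Gata3 and Cd4 whatever their values, and a further item of the rule is not reported here. Predicted gene models and receptor segments are counted but not named. Of 29 gene lists, 27 were tested with camera at a preset correlation of 0.01, with adjustment over the lists of a comparison. Mitochondrially encoded transcripts had 0 measured members, and the sex-linked list served as a sample check. Camera with an estimated correlation and fry were run beside it. Counts adjusted over the list alone use the same p-values with adjustment over the members of that list. Among lists that were not shifted, the median and the mean had opposite signs for the regulatory T cell and the NK and CD8 T cell lists in IL6_ConCM against ConCM, for the VEGF and PlGF list in PlGFCM against ConCM and against IL6_ConCM, and for the amino acid and ER chaperone lists in PlGFCM against IL6_ConCM.

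The overlap and the correlation of fold changes that shared controls give with unchanged groups were simulated in 100 draws. The fit was tested on simulated data for PlGFCM against ConCM with 200 of 22180 genes changed in each of 20 runs. With variances drawn from limma's own model, 24.6% of changes of 0.5 log2 units, 89.5% of those of 1 and 98.8% of those of 1.5 were recovered, and 5.01% of calls were false. Drawn from the moderated variances instead, 8.21% of calls were false, and drawn from the residual variances 2.92%, so the true share of false calls depends on how gene variances spread. A list of 19 genes lowered by 0.3 log2 units passed in 20 of 20 runs with independent genes, and 0 of 520 tests of unshifted lists passed.

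Alternatives were quantile normalization, subtraction of array medians, filters on low levels at the median and the 25th percentile of all probe sets, the mean of all probe sets per gene, all probe sets tested singly, eBayes without a trend or with a robust prior, the arrays of the compared groups alone, array weights, the replicate number as a block, an unadjusted p under 0.05 with at least 2-fold change, each array left out in turn and, added after the data were examined, the ConCM arrays divided between the comparisons for the correlation of fold changes. Where this leaves a group with 1 array, that array is assumed to vary like the other groups. Figures were drawn with matplotlib.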

Results

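Gene expression was measured in CD4+ T cells of mouse spleen that were isolated with magnetic beads and stimulated through CD3 and CD28 for 12 hours in conditioned medium. Placental growth factor (PlGF) is a ligand of the VEGF family that binds the receptor Flt1 and the co-receptor Nrp1. The medium with PlGF (PlGFCM) came from HEK-293 cells, a human embryonic kidney line, made to overexpress the PlGF2 form. The other cells received control conditioned medium, either alone (ConCM) or with IL-6 at 20 ng/ml (IL6_ConCM). Each group held 2 replicate samples, 6 arrays in all, and 22180 genes were tested. The median log2 level ran from 5.47 to 5.51 over the arrays. Across the 22180 genes, which are not independent replicates, Pearson's r was 0.994 to 0.995 within a group and 0.993 to 0.995 between groups. Arrays of 1 group were thus not clearly closer to each other than to the rest. The number of arrays limits the precision of every value given here.

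Sex-linked transcripts set 1 array apart. Xist, which is transcribed from the inactive X chromosome of female cells, had a log2 level of 8.38 on PlGFCM replicate 2 and of 3.58 to 3.95 on the other 5 arrays. The Y-linked genes Uty, Kdm5d and Eif2s3y were each lowest on the same array, at 7.50, 7.07 and 8.59. On the other 5 arrays Uty lay between 7.77 and 8.14, Kdm5d between 7.42 and 7.77 and Eif2s3y between 8.90 and 9.14.

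**Figure D1:**
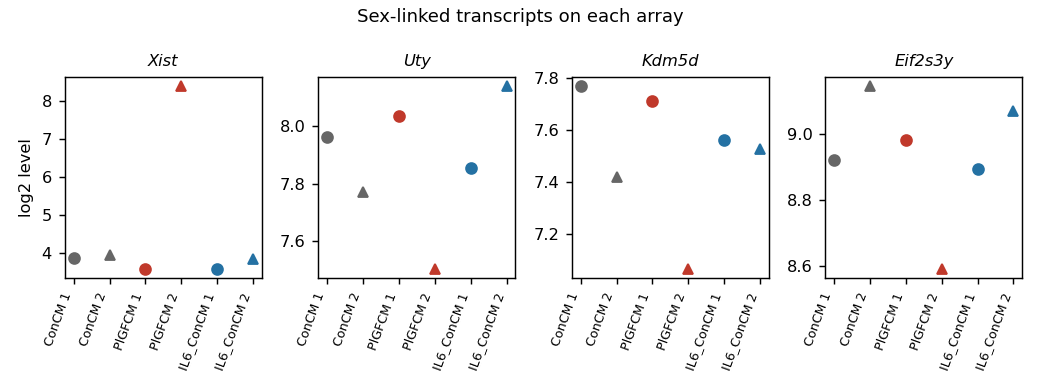
Log2 level of Xist and of the Y-linked genes Uty, Kdm5d and Eif2s3y on each of the 6 arrays, with 1 point per array and a separate vertical scale per gene. Xist stands at 8.38 on PlGFCM replicate 2 and at no more than 3.95 elsewhere, and all 3 Y-linked genes are lowest on that array.

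The comparison of PlGFCM with ConCM asked what medium with PlGF changes in stimulated CD4+ T cells. The gene with the largest increase was Hamp, which encodes the iron-regulating hormone hepcidin. Its log2 level was 5.27 ± 0.20 (SD, n = 2) in ConCM and 7.72 ± 0.27 in PlGFCM, a log2 change of 2.44 ± 0.17 (SE) or 5.45-fold, with a limma adjusted p of 9.6e-05. Il10, a cytokine gene, rose by 1.14, Il17f, also a cytokine gene, by 1.04 and Ccl3, a chemokine gene, by 1.37. Eomes, a transcription factor of cytotoxic and Th1 cells, fell by 1.34 from a log2 level of 7.75 ± 0.35 to 6.40 ± 0.11, and Gzmb, the cytotoxic protease granzyme B, fell by 0.81. In all, 96 genes changed, of which 78 rose and 18 fell, and 20 changed by at least 2-fold. Of the 96, 7 were predicted gene models or receptor segments. An unadjusted p under 0.05 was reached by 1938 genes (8.74%), where a share of 0.05 is expected with no gene changed. Of these, 930 were higher and 1008 lower, so the excess of increases among the genes that passed was not seen there. Without PlGFCM replicate 2 the number was 12, all of them among the 96 and all higher, so none of the 18 genes that fell, Eomes and Gzmb included, passed without this array, nor did Il10, Il17f or Ccl3. Hamp passed without it. Without PlGFCM replicate 1, Eomes, Gzmb, Il10 and Il17f did not pass, and without ConCM replicate 2, Il10, Il17f and Ccl3 did not. Ccl3 did not pass after quantile normalization, with a robust prior or without ConCM replicate 1 either, and passed in 10 of 18 alternatives. The number was 22 without PlGFCM replicate 1, 62 without ConCM replicate 1 and 15 without ConCM replicate 2. Fitted without an intensity trend 6 genes passed, with all probe sets tested singly 5 passed, and with genes at or above the median level alone 174 passed.

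Further genes with large increases in PlGFCM were Ly6g, at a log2 change of 1.62 ± 0.11 (SE), Emp1 at 1.44 ± 0.09, Ctsw, which encodes the protease cathepsin W, at 1.35 ± 0.08, and Timp1, an inhibitor of metalloproteinases, at 1.12 ± 0.11. Olfr1303 rose by 1.14, Serpinb5 by 1.05 and Atp2b4, a plasma membrane calcium pump, by 1.04. The probe sets of Ly6g and Olfr1303 belong to families of similar sequence, so these assignments are uncertain. Besides Eomes and Gzmb, the genes with the largest decreases were Akr1c18, a hydroxysteroid dehydrogenase, at -1.25 ± 0.15, Fcer2a at -0.86 ± 0.13, Ms4a1, the B cell antigen CD20, at -0.84 ± 0.12, Ms4a4b at -0.74 and the interferon-induced gene Ifit1 at -0.73. Ccl24 fell by 0.65, Clec7a, a receptor of myeloid cells, by 0.60 and Lad1 by 0.59. Without PlGFCM replicate 2, Ly6g, Emp1, Ctsw, Timp1 and Atp2b4 passed, and Olfr1303 and Serpinb5 did not. Without ConCM replicate 2, Hamp, Ly6g, Emp1, Ctsw, Timp1, Atp2b4, Eomes and Gzmb passed, and Olfr1303, Serpinb5 and the other decreases named here did not. Ly6g, Emp1 and Ctsw passed in all 18 alternatives, and Hamp in 17 of 18 with adjusted p from 2.5e-05 to 0.0530.

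On the list of Th17 cells, the helper T cells that make IL-17, 5 of 23 measured genes rose in PlGFCM and 18 did not pass, and 12 rose when adjusted over the list alone. The 5 were Il10, Il17f, Il1r1, which encodes the IL-1 receptor, at a log2 change of 0.74, and the transcription factors Ahr at 0.85 and Maf at 0.85. None of the 5 passed without ConCM replicate 2, without PlGFCM replicate 1 or without PlGFCM replicate 2. The list as a whole was shifted upwards by camera with a median of 0.21 (adjusted p = 2.0e-12), and its adjusted p = 0.125 with an estimated correlation. Il17a was at 0.47 (adjusted p = 0.376) and Il21 at 0.74 (adjusted p = 0.271), which did not pass. The IL-6 and STAT3 list was also shifted upwards, with a median of 0.17 (adjusted p = 5.0e-09), and adjusted p = 0.125 with an estimated correlation. Of its 22 measured members 3 rose, namely Il6ra, the IL-6 receptor chain, by 0.41, Socs3, a feedback inhibitor of cytokine signalling, by 0.49, and Maf, and none of these passed when any 1 of the 4 arrays compared was left out. Adjusted over the list alone, 11 rose and 1 fell. Stat3, Batf, Maf, Il21 and Hif1a are on both this list and the Th17 list, so the shifts of these lists are not independent. Without PlGFCM replicate 2 the Th17 and the IL-6 and STAT3 lists were still shifted by camera (adjusted p = 3.5e-10 and 1.9e-06). Stat3 itself was at 0.18 (adjusted p = 0.325), Il6st at 0.21 (adjusted p = 0.406) and Il6 at 0.36 (adjusted p = 0.523).

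Of 18 measured genes on the regulatory T cell list 1 rose, Il10, which several helper subsets express, and 5 rose when adjusted over the list alone. The list was shifted upwards with a median of 0.18 (adjusted p = 5.9e-10, and adjusted p = 0.30 with an estimated correlation). Its defining factor Foxp3 was at 0.20 (adjusted p = 0.610). Of 16 Th1 genes 2 fell, Eomes and Gzmb, none rose, and adjusted over the list alone 1 rose and 2 fell. Il10, Eomes and Gzmb did not pass without PlGFCM replicate 1 or without PlGFCM replicate 2. The Th1 list was not shifted (adjusted p = 0.184), and Tbx21, the Th1 factor, was at -0.25 (adjusted p = 0.592). Gata3, the Th2 factor, was at -0.24 (adjusted p = 0.575) and Cd4 at -0.08 (adjusted p = 0.832). The cells' own Pgf was at 0.15 (adjusted p = 0.873), Flt1 at -0.04 (adjusted p = 0.962) and Nrp1 at 0.17 (adjusted p = 0.883), and none of the 10 measured VEGF and PlGF ligands and receptors passed.

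**Figure D2:**
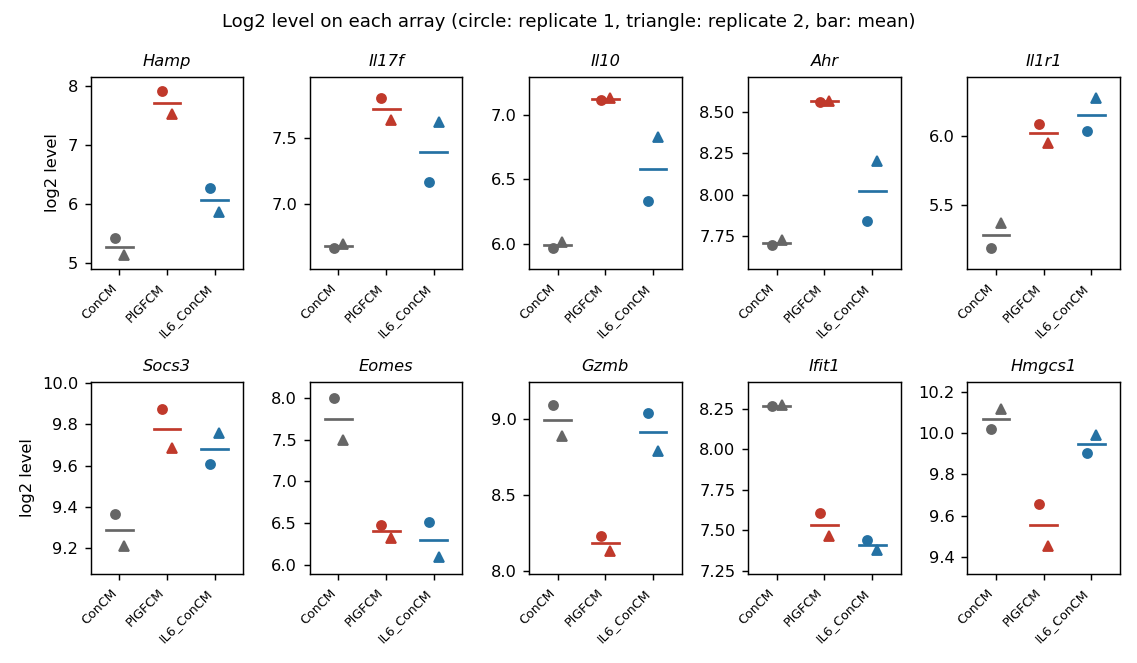
Log2 level of 10 genes on each array by group, with circles for replicate 1, triangles for replicate 2, a bar at the mean of the 2 arrays and a separate vertical scale per gene. Hamp is higher in PlGFCM than in both other groups, Eomes and Ifit1 are lower in both treated groups than in ConCM, and Hmgcs1 fell in PlGFCM against ConCM.

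On the cholesterol synthesis list all 19 measured genes had a negative log2 change, 4 fell, and 13 fell when adjusted over the list alone. Hmgcs1, which makes HMG-CoA, fell by 0.51, Fdps by 0.49, Dhcr7 by 0.44 and Insig1, a regulator of the pathway, by 0.42, and none of these 4 passed when any 1 of the 4 arrays compared was left out. The list's median was -0.29 (camera adjusted p = 1.5e-16, and adjusted p = 0.260 with an estimated correlation). The median was -0.23 without PlGFCM replicate 2 (adjusted p = 3.5e-08). The type I interferon list had a median of -0.23 (adjusted p = 2.0e-12, and adjusted p = 0.205 with an estimated correlation). Of its 27 measured members 2 fell, Ifit1 and Usp18 at -0.48, and 10 fell when adjusted over the list alone. Neither passed without PlGFCM replicate 2 or without ConCM replicate 2, and Usp18 did not pass without ConCM replicate 1 or PlGFCM replicate 1 either. No gene of ribosome biogenesis or of the G1 and S phases passed singly over all genes tested. Their lists were shifted downwards with medians of -0.25 and -0.22, and adjusted over the list alone 11 of 21 and 13 of 25 members fell. For these lists camera gave adjusted p = 4.0e-14 and 1.0e-09, against adjusted p = 0.30 and 0.329 with an estimated correlation.

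Across the 27 lists tested, 12 were shifted between PlGFCM and ConCM, 8 upwards and 4 downwards, and without PlGFCM replicate 2 the number was 12, of which 11 were the same lists in the same direction. With an estimated correlation 0 of the 12 passed, and the lists of IL-6 and STAT3, of naive and quiescent T cells and of NF-kappaB passed with fry, which tests whether a list's genes move on balance 1 way. The naive and quiescent list had a median of 0.17 (camera adjusted p = 8.7e-06) and the NF-kappaB list one of 0.11 (adjusted p = 0.000179). The immediate early list, which was set as a check on sample handling, had one of 0.24 (adjusted p = 2.2e-05). With an estimated correlation these 3 lists had adjusted p = 0.125, 0.127 and 0.125. A member of each rose, namely S1pr1, which encodes a receptor for exit from lymph nodes, by 0.44, Ccl3, and Ier3 by 0.75, and each lost its call when single arrays were left out. S1pr1 did not pass without ConCM replicate 2, PlGFCM replicate 1 or PlGFCM replicate 2, Ccl3 without ConCM replicate 1, ConCM replicate 2 or PlGFCM replicate 2, and Ier3 without ConCM replicate 1, ConCM replicate 2 or PlGFCM replicate 1. Adjusted over the list alone, 5 rose and 1 fell on the naive list, 4 rose on the NF-kappaB list and 3 on the immediate early list. The lists of T cell identity, with a median of 0.07, and of glycolysis and hypoxia, with a median of 0.06, were shifted upwards with none of their members passing (adjusted p = 0.0203 and 0.0200, and adjusted p = 0.527 and 0.591 with an estimated correlation). The T cell identity call was lost without ConCM replicate 2, where its median turned negative (-0.0072, adjusted p = 0.705), PlGFCM replicate 1 (0.0743) or PlGFCM replicate 2 (0.0748), and the glycolysis call without ConCM replicate 1 (0.346) or PlGFCM replicate 1, where its median turned negative (-0.015, adjusted p = 0.777). Both were also lost with genes at or above the median level alone (0.0625 and 0.0700). The other 15 lists, with adjusted p from 0.0757 to 0.971, were not shifted. These were Th1, Th2, follicular helper, T cell activation, mitosis, amino acid and integrated stress response, ER chaperones, heat shock, VEGF and PlGF ligands and receptors, p53 response and the markers of B cells, myeloid cells, dendritic cells, NK and CD8 T cells, and erythroid cells and platelets. Among B cell markers 2 of 16 fell, Ms4a1 and Fcer2a, while 13 of 16 had a positive log2 change. Among NK and CD8 T cell markers Gzma, the protease granzyme A, rose by 0.93 and Eomes fell. None of these 4 genes passed without PlGFCM replicate 1 or without PlGFCM replicate 2.

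The comparison of IL6_ConCM with ConCM asked what added IL-6 changes. Serpinb5, a member of the serpin family, rose by 1.65 ± 0.16 (SE), from a log2 level of 4.41 ± 0.10 (SD, n = 2) to 6.06 ± 0.31. Ly6g rose by 1.36, Olfr1303 by 1.15, Gzma by 1.12, the mucin gene Muc1 by 1.05 and Plac8 by 1.01. Eomes fell by 1.44, the activation-induced nuclear receptor Nr4a3 by 0.91, and the interferon-induced genes Ifit1, Oasl2 and Usp18 by 0.86, 0.77 and 0.68. In all, 25 genes changed, of which 19 rose and 6 fell, 2 of them predicted models. An unadjusted p under 0.05 was reached by 1247 genes (5.62%), 582 of them higher and 665 lower, where a share of 0.05 is expected with no gene changed. Of the genes that passed, 7 rose and 5 fell with the arrays of these groups alone, 13 rose and 11 fell without IL6_ConCM replicate 1, and 3 rose and 3 fell without IL6_ConCM replicate 2. Without PlGFCM replicate 2, which enters here through the shared estimate of the spread, 12 genes passed, and 11 of these were among the 25. The number was 12 without PlGFCM replicate 1, 41 without ConCM replicate 1, 2 without ConCM replicate 2 and 6 without IL6_ConCM replicate 2. It was 1 without an intensity trend, 0 with all probe sets tested singly by limma, 12 with the arrays of these groups alone, 47 with array weights, and 53 under either filter on low levels. Without ConCM replicate 2, Ly6g and Eomes were the genes that passed, and of the genes named for this comparison Serpinb5, Ly6g, Gzma, Nr4a3 and Usp18 passed without IL6_ConCM replicate 2. Oasl2 did not pass when any 1 of the 6 arrays was left out, and Olfr1303 and Plac8 did not pass without PlGFCM replicate 1 or without PlGFCM replicate 2.

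Other genes that rose with IL-6 were Fam240a by 0.97, the long non-coding RNA Morrbid by 0.92, Il1r1 by 0.87 and Emp1 by 0.86, and Lad1 fell by 0.76. Il1r1 did not pass when any 1 of the 6 arrays was left out. Morrbid passed in 1 of the 6 fits without an array, that without ConCM replicate 1, and did not pass after quantile normalization. Fam240a, Emp1 and Lad1 did not pass without ConCM replicate 2 or IL6_ConCM replicate 2, and Lad1 not without PlGFCM replicate 1 or PlGFCM replicate 2. Socs3 was at 0.40 (adjusted p = 0.217), Il17f at 0.71 (adjusted p = 0.108), Il17a at 0.21 (adjusted p = 0.993), Il21 at 0.83 (adjusted p = 0.339) and Il6ra at 0.36 (adjusted p = 0.101), none of which passed. Stat3 was at 0.08 (adjusted p = 0.988), Il6st at 0.01 (adjusted p = 1.000), Foxp3 at 0.06 (adjusted p = 1.000), Tbx21 at -0.52 (adjusted p = 0.230), Gata3 at -0.13 (adjusted p = 0.997) and Il6 at -0.58 (adjusted p = 0.379). Pgf was at 0.34 (adjusted p = 0.920), Flt1 at -0.22 (adjusted p = 0.981), Nrp1 at -0.19 (adjusted p = 0.997) and Cd4 at -0.07 (adjusted p = 0.997).

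Interferon-induced genes were the list with the strongest shift under IL-6. Their mean deviation from the mean of the 6 arrays was 0.27 and 0.13 in ConCM, -0.06 and -0.07 in PlGFCM and -0.11 and -0.15 in IL6_ConCM. The same ConCM arrays enter both comparisons against ConCM, so high values on them lower this list in both. Shifts that other lists show in both comparisons carry the same limit. Of 27 measured, 3 fell, Ifit1, Oasl2 and Usp18, none of which passed without ConCM replicate 2, 15 fell when adjusted over the list alone, and the median was -0.34 (camera adjusted p = 9.9e-22, and adjusted p = 0.239 with an estimated correlation). Of 23 Th17 genes 1 rose, Il1r1, which did not pass when any 1 of the 6 arrays was left out, with the arrays of these groups alone or with a replicate block, and 6 rose when adjusted over the list alone. On the IL-6 and STAT3 list none of 22 passed over all genes tested, and 7 rose and 1 fell when adjusted over the list alone. Both lists were shifted upwards, with medians of 0.10 and 0.12 (adjusted p = 2.7e-06 and 2.6e-06, and adjusted p = 0.239 for both with an estimated correlation). As these lists share Stat3, Batf, Maf, Il21 and Hif1a, their shifts are not independent. The Th1 list had a median of -0.11 (adjusted p = 0.00374, and adjusted p = 0.348 with an estimated correlation), with Eomes the member that fell, though not without IL6_ConCM replicate 2, and 5 lower when adjusted over the list alone. T cell activation genes had a median of -0.12 (adjusted p = 2.2e-05, and adjusted p = 0.348 with an estimated correlation), with Nr4a3 the member that fell, though not without ConCM replicate 2, and 4 lower when adjusted over the list alone.

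Across the 27 lists 11 were shifted between IL6_ConCM and ConCM, 4 upwards and 7 downwards, the same 11 were shifted without PlGFCM replicate 2, and 0 of them passed with an estimated correlation or with fry. Besides those named, ribosome biogenesis (median -0.16, adjusted p = 2.0e-07), G1 and S phase (-0.12, adjusted p = 1.4e-05), cholesterol synthesis (-0.08, adjusted p = 0.0242) and dendritic cell markers (-0.10, adjusted p = 0.0306) were shifted downwards. T cell identity (median 0.10, adjusted p = 0.00232) and immediate early genes (0.10, adjusted p = 0.0478) were shifted upwards. With an estimated correlation these 6 had adjusted p = 0.588, 0.588, 0.754, 0.348, 0.588 and 0.359, and none of their members passed singly. Without IL6_ConCM replicate 2 the calls of the Th1 list (adjusted p = 0.0708), G1 and S phase (0.195) and ribosome biogenesis (0.259) were lost. Those of cholesterol synthesis, dendritic cell markers and T cell identity were lost without ConCM replicate 2 (0.541, 0.196 and 0.492) or IL6_ConCM replicate 1 (0.202, 0.362 and 0.473), and that of immediate early genes when any 1 of the 4 arrays compared was left out (0.0856 to 0.123). The immediate early call was also lost after quantile normalization (0.0503), with array medians subtracted (0.0515) and with a replicate block (0.0674). With genes at or above the median level alone it was lost too (0.0796), as was that of dendritic cell markers (0.0539). The other 16 lists were not shifted, with adjusted p from 0.0777 to 0.708. They included the regulatory T cell list, with a median of -0.05 and a mean of 0.03, and the markers of B cells, myeloid cells, NK and CD8 T cells, and erythroid cells and platelets.

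The changes against ConCM were compared with each other to ask whether PlGFCM and IL-6 moved the same genes. Of the genes that changed, 23 passed in both comparisons, 18 higher in both and 5 lower in both. Among them were Ly6g, Emp1, Serpinb5, Gzma, Muc1, Il1r1 and Atp2b4, which rose, and Eomes, Ifit1, Usp18, Nr4a3 and Lad1, which fell. Independent lists of these lengths would share 0.0668 genes that rose and 0.00487 that fell. In simulations in which neither treatment changed any gene, the comparisons shared 0.01 genes on average and 1 at most in 100 draws. With no gene changed, hardly any gene passes in either comparison, so this simulated overlap was bound to be small. Neither value shows how many of the 23 genes coincide through the noise of the shared ConCM arrays. Across genes, which are not independent replicates, the fold changes correlated with a Pearson's r of 0.591, where the shared arrays alone gave 0.50. Their covariance was 0.0165 against 0.00984 simulated, a difference of 0.00663. With 1 ConCM array as the control of each comparison, a split added after the data were examined, r fell to 0.117 or 0.148 and the covariance to 0.00462 or 0.00572, depending on which array served which comparison, and 53.9% or 55.3% of genes had the same sign. Genes that passed in both were counted with the shared controls. Their number was 3 without PlGFCM replicate 2, 5 without PlGFCM replicate 1, 2 without ConCM replicate 2, 5 without IL6_ConCM replicate 2 and 38 with genes at or above the median level alone, and r was 0.720 without ConCM replicate 2 and 0.476 without IL6_ConCM replicate 2.

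**Figure D3:**
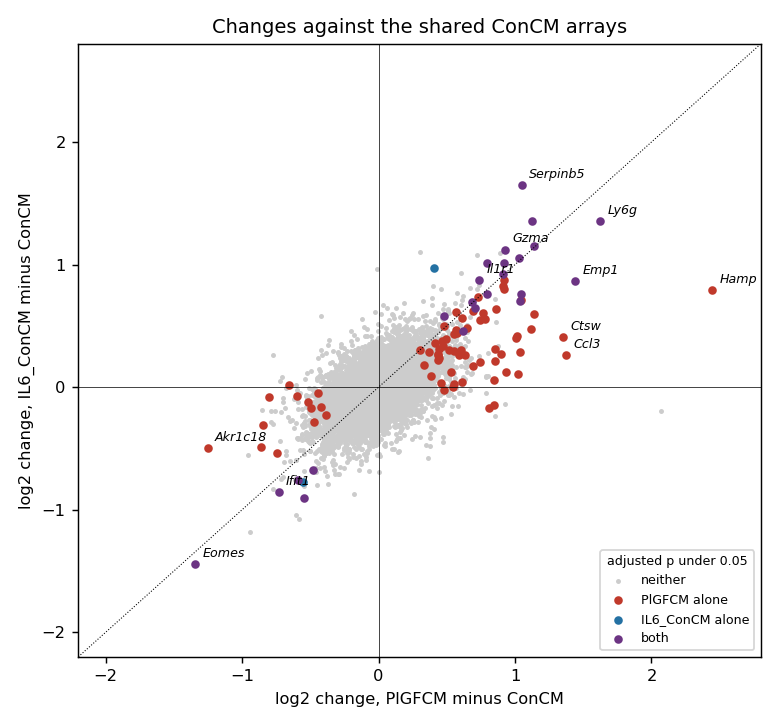
Log2 change of each of 22180 genes in PlGFCM (horizontal axis) and in IL6_ConCM (vertical axis), both against the same ConCM arrays, with genes past the threshold in colour and the dotted line marking equal changes. The 23 genes that passed in both lie in the quadrants of equal sign, and Hamp lies far to the right of the line.

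The direct comparison of PlGFCM with IL6_ConCM asked how the treatments differ from each other. Hamp was higher in PlGFCM by 1.65 ± 0.17 (SE), with a log2 level of 6.06 ± 0.29 (SD, n = 2) in IL6_ConCM. That level lay between those of ConCM and PlGFCM, and Hamp did not pass for IL6_ConCM against ConCM. Higher in PlGFCM were also Cpt1a, which acts in the import of fatty acids into mitochondria, by 0.92, Ctsw by 0.94 and the cytokine gene Il1a by 0.98. So were Clec4e, a receptor of myeloid cells, by 0.99, Aqp3, a water and glycerol channel, by 0.81 and Cpd by 0.78. These 7 genes were the ones that passed, and 0 were lower by limma. At an unadjusted p under 0.05 were 4.37% of all genes, 401 of them lower, where a share of 0.05 is expected with no gene changed. After quantile normalization 7 genes passed as higher and 1 as lower. The lower genes with the smallest p, which did not pass, were Gzmb at -0.73 (adjusted p = 0.0613), Ccl24 at -0.67 (adjusted p = 0.119), Vmn1r25 at -0.97 (adjusted p = 0.122), Fpr-rs4 at -1.0 (adjusted p = 0.137) and Akr1c18 at -0.76 (adjusted p = 0.199). No gene passed by limma without PlGFCM replicate 2, without IL6_ConCM replicate 2, without an intensity trend or with all probe sets tested singly, 4 passed without IL6_ConCM replicate 1 and 5 without PlGFCM replicate 1, of which 1, Ctsw, was among the 7, and 969 genes had an unadjusted p under 0.05 in the fit on all arrays. Without IL6_ConCM replicate 1, Hamp, Ctsw, Cpt1a and Il1a passed, and Aqp3 and Cpd did not pass when any 1 of the 6 arrays was left out.

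Genes called against ConCM in PlGFCM alone were therefore not shown to differ from IL-6 unless they are among these 7. Il17f differed by 0.33 (adjusted p = 0.998), Il17a by 0.26, Socs3 by 0.10, Il6ra by 0.05, Stat3 by 0.10, Il6st by 0.20, Il21 by -0.10, Foxp3 by 0.14, Tbx21 by 0.26, Gata3 by -0.11 and Cd4 by -0.01, each with an adjusted p of 0.998. Pgf differed by -0.19, Flt1 by 0.18 and Nrp1 by 0.35, each also with an adjusted p of 0.998. Il6 was at 0.94 (adjusted p = 0.107).

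On the cholesterol synthesis list all 19 genes had a negative log2 change in PlGFCM against IL6_ConCM, with a median of -0.26, none passed singly over all genes tested, and 11 were lower when adjusted over the list alone (camera adjusted p = 2.8e-17, and adjusted p = 0.242 with an estimated correlation). The regulatory T cell list was shifted upwards with a median of 0.19 and 7 of 18 members higher when adjusted over the list alone (adjusted p = 3.9e-11, and adjusted p = 0.255 with an estimated correlation). The NF-kappaB list was shifted upwards with a median of 0.13 (adjusted p = 6.0e-08, and adjusted p = 0.226 with an estimated correlation), as were the naive and quiescent list with 0.11 (adjusted p = 0.000263) and T cell activation with 0.10 (adjusted p = 1.9e-05), both at adjusted p = 0.242 with an estimated correlation. Myeloid markers were shifted upwards with a median of 0.08 (adjusted p = 0.0122) and B cell markers with 0.17 (adjusted p = 0.0293), both at adjusted p = 0.242 with an estimated correlation.

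Across the 27 lists 14 were shifted between PlGFCM and IL6_ConCM, 11 upwards and 3 downwards. With an estimated correlation 0 passed, and 2 passed with fry, the naive and quiescent list and the NF-kappaB list. The remaining upward shifts were of Th17 genes (median 0.08, adjusted p = 0.000100), IL-6 and STAT3 (0.03, adjusted p = 0.0367), interferon-induced genes (0.09, adjusted p = 0.00915), p53 response (0.05, adjusted p = 0.0367) and immediate early genes (0.13, adjusted p = 0.00117). The remaining downward shifts were of G1 and S phase (-0.10, adjusted p = 0.00227) and ribosome biogenesis (-0.09, adjusted p = 0.000100). With an estimated correlation these 7 had adjusted p = 0.242, 0.242, 0.534, 0.245, 0.242, 0.568 and 0.553. Adjusted over the list alone, 5 Th17 genes, 4 T cell activation genes, 2 myeloid genes and 1 gene each of the NF-kappaB, IL-6 and STAT3, and p53 lists were higher, and 1 B cell gene was lower. Without PlGFCM replicate 1, 8 lists were shifted, and the Th17, interferon, B cell, myeloid, p53, immediate early and IL-6 and STAT3 calls were lost (adjusted p from 0.0515 to 0.431). Without PlGFCM replicate 2, 12 lists were shifted, 10 of them the same, and the IL-6 and STAT3 (adjusted p = 0.0608), myeloid (0.0608), p53 (0.217) and G1 and S phase (0.532) calls were lost. Without IL6_ConCM replicate 2 those of the interferon (0.0784), myeloid (0.149) and p53 (0.189) lists were lost. Without IL6_ConCM replicate 1 the calls of the ribosome biogenesis, G1 and S phase, B cell, and IL-6 and STAT3 lists were lost. The median of ribosome biogenesis then turned barely positive, at 0.0032. After quantile normalization the IL-6 and STAT3 (0.0698) and p53 (0.0757) calls were lost. The other 13 lists had adjusted p from 0.0862 to 0.979.

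**Figure D4:**
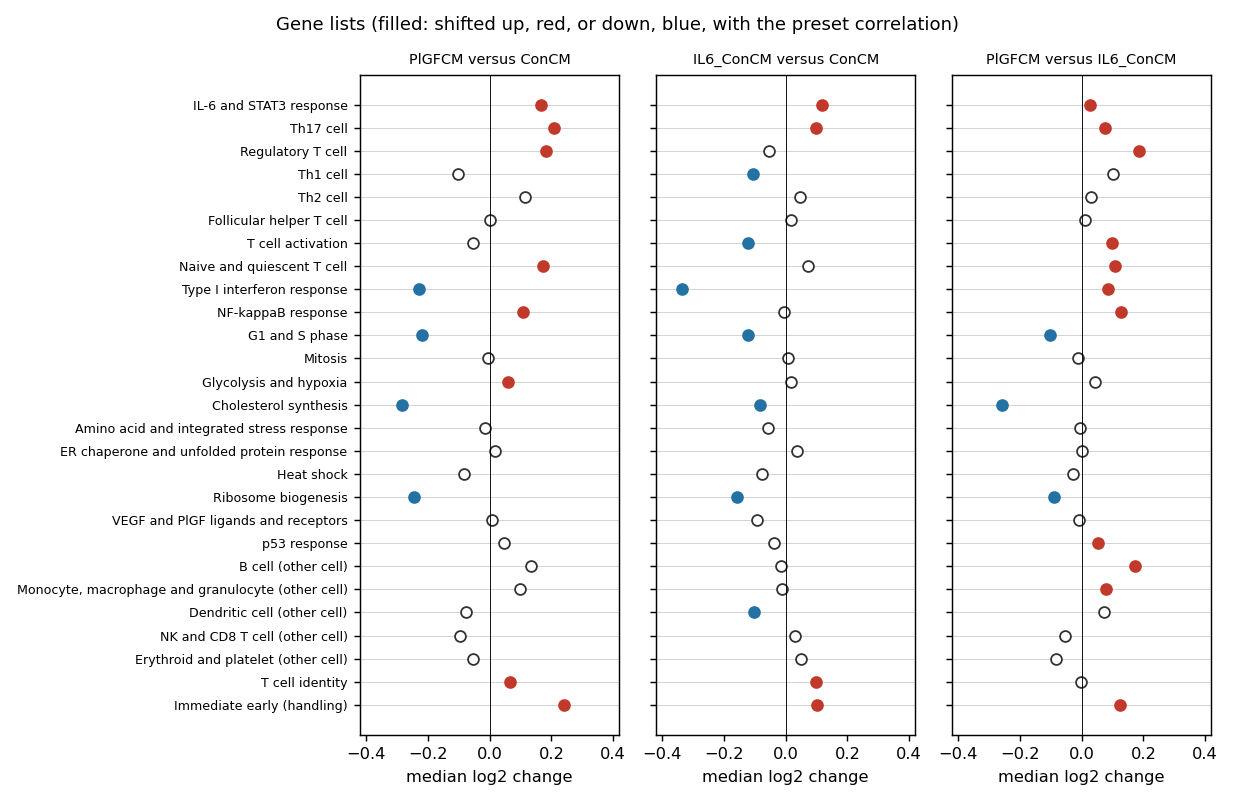
Median log2 change of the measured members of each of 27 gene lists in the 3 comparisons, with filled points for lists shifted by camera with a preset correlation of 0.01 (red upwards, blue downwards) and open points for the rest. Cholesterol synthesis lies at -0.29 and -0.26 in the comparisons of PlGFCM with ConCM and with IL6_ConCM and at -0.08 for IL6_ConCM against ConCM, and 0 of the shifts held with an estimated correlation.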

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

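The replicate numbers appear only in sample titles, and deviations of equally numbered arrays correlated at -0.04 for ConCM with PlGFCM, 0.11 for ConCM with IL6_ConCM and 0.03 for PlGFCM with IL6_ConCM, so they were not taken to pair the arrays. With a replicate block, 62 genes passed for PlGFCM against ConCM, 16 for IL6_ConCM against ConCM, 5 for PlGFCM against IL6_ConCM and 14 in both comparisons against ConCM, and 12, 10 and 14 lists were shifted.

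For PlGFCM against ConCM the count of 96 became 174 with genes at or above the median level, 5 with all probe sets tested singly, 6 without an intensity trend and 20 at an unadjusted p under 0.05 and at least 2-fold. For IL6_ConCM against ConCM the count of 25 became 53 under either filter on low levels and 0 with all probe sets tested singly by limma. In the fit per gene, 1247 genes (5.62%) had an unadjusted p under 0.05. The count became 1 without a trend, 12 with the compared groups alone, 47 with array weights and 15 at an unadjusted p with 2-fold. For PlGFCM against IL6_ConCM the count of 7 became 0 by limma with all probe sets tested singly and 0 without a trend. In the fit per gene, 969 genes (4.37%) had an unadjusted p under 0.05. With no gene changed a share of 0.05 is expected, so this comparison showed no excess of small p-values. The number passing in both became 38 with genes at or above the median level. The filters test fewer genes and testing all probe sets tests more. The cause of the other shifts was not tested. With 1 array left out, the counts ran from 12 to 107, from 2 to 41 and from 0 to 5 in the 3 comparisons, from 2 to 32 in both, and the correlation of fold changes from 0.476 to 0.720. With the ConCM arrays divided between the comparisons, an alternative chosen after seeing the data, that correlation was 0.117 with ConCM replicate 1 as the control of PlGFCM and 0.148 with ConCM replicate 2, since the noise of the same control arrays then no longer enters both fold changes and each fold change rests on 1 control array. The lists shifted ran from 11 to 14, from 8 to 11 and from 8 to 15. With an estimated correlation 0 lists passed in each comparison, and with fry 3, 0 and 2.

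Of 105 named results, 58 passed, and most of these lost their call in at least 1 fit without an array. All 58 kept their direction in every alternative. Every gene that passed had groups that do not overlap, so leaving out 1 array could not reverse its direction. The kept directions therefore do not measure stability. Of the results that did not pass, 11 changed sign when an array was left out, and the cause was not tested. For PlGFCM against ConCM, without 1 array Pgf ran from -0.026 to 0.32, Flt1 from -0.18 to 0.098, Nrp1 from -0.15 to 0.49 and Cd4 from -0.20 to 0.032. For IL6_ConCM against ConCM, Nrp1 ran from -0.51 to 0.13, Il6st from -0.080 to 0.092, Foxp3 from -0.080 to 0.20 and Gata3 from -0.30 to 0.032. For PlGFCM against IL6_ConCM, Il21 ran from -0.35 to 0.15, Gata3 from -0.28 to 0.055 and Cd4 from -0.12 to 0.11.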

Other observations

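The genes of this part were picked after their values were seen, as were the tests of the Y-linked genes, of Xist on PlGFCM replicate 1, of the myeloid markers and of PlGFCM replicate 1 for the inflammatory and SMAD genes. The tests of the second Xist probe set, of the calls without PlGFCM replicate 2 and of the TGF-beta and BMP target lists were written before their results were seen.

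These genes were picked from those that passed, no list of them was tested, and the names of pathways serve only to say what each gene does. In PlGFCM against ConCM, Cpt1a rose by 1.02 (limma adjusted p = 0.00109) and Slc25a20, the carnitine carrier that works next to it in the import of fatty acids into mitochondria, by 0.48 (adjusted p = 0.0401), while under IL-6 they were at 0.11 and -0.02. Cpt1a passed in all 6 fits without an array and Slc25a20 in none. The IL-1 genes Il1a and Il1b rose by 0.81 and 0.61 and were at -0.17 and 0.04 under IL-6. Neither passed against ConCM without ConCM replicate 2, PlGFCM replicate 1 or PlGFCM replicate 2, and Il1b not without ConCM replicate 1. Malt1 and Map3k8, which act in signalling to NF-kappaB, rose in both treatments, by 0.62 and 0.48 in PlGFCM and by 0.46 and 0.58 under IL-6. In PlGFCM, Malt1 did not pass without PlGFCM replicate 2, and Map3k8 not without ConCM replicate 2, PlGFCM replicate 1 or PlGFCM replicate 2, and under IL-6 each passed in 1 of the 6 fits without an array, that without ConCM replicate 1. Smad7, Skil, Pmepa1 and Ldlrad4, which restrain or report SMAD signalling, rose by 0.59, 0.55, 0.69 and 0.74 in PlGFCM, and were at 0.26, 0.00, 0.17 and 0.21 under IL-6, where none passed. None of these 4 passed in PlGFCM without ConCM replicate 2, PlGFCM replicate 1 or PlGFCM replicate 2, and Smad7, Skil and Ldlrad4 not without ConCM replicate 1. Ldlrad4 did not pass after quantile normalization either. The direct differences of these 4 genes between PlGFCM and IL6_ConCM did not pass either, with adjusted p of 0.0654 for Skil and 0.199 to 0.604 for the rest.

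Xist stood at 8.38 on PlGFCM replicate 2 and between 3.58 and 3.95 on the other 5 arrays. Female cells in place of male cells are argued against by Uty, Kdm5d and Eif2s3y, whose mean lay at -0.47 log2 units against the other arrays, and a response of Xist to PlGFCM by PlGFCM replicate 1, at -0.36 against the highest array of the other groups. A mixture of female with male cells is a candidate explanation, since 3 of 3 Y-linked genes were lowest on this array, at 72.4% of their level on the others on average. The X-linked genes Kdm6a, Kdm5c, Eif2s3x and Ddx3x lay 0.089 higher on it on average. The median absolute difference of genes between any pair of arrays was at least 0.109, so this small value does not bear on the question. A fault of 1 probe set stays open, because the second probe set for Xist, shared with Tsix, lay 0.062 above the highest of the other arrays and between 4.40 and 4.54 on all of them. Whether female cells on PlGFCM replicate 2, if present, contribute to the genes called between PlGFCM and ConCM stays open: 100% of the 12 called without this array moved the same way on it, but they come from a fit that does not contain it, so this decides nothing about the calls that need it.

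Il1a, Il1b, Clec4e, Il6 and Fpr2 had a median log2 change of 0.94 in PlGFCM against IL6_ConCM, of which Il1a and Clec4e passed. Against ConCM, Il6 was at 0.36 in PlGFCM and -0.58 in IL6_ConCM, and Fpr2 at 0.47 and -0.44, none of which passed. The differences of Il6 and Fpr2 between the treatments thus rest in part on lower values with IL-6. A larger share of myeloid cells left after the magnetic isolation stays open. The 11 myeloid markers above a log2 level of 6 had a median of 0.08, with quartiles of -0.01 and 0.25. This median lay at -0.86 against that of the 5 genes. The 5 genes were picked for high values in PlGFCM and the markers were not, so a gap was likely beforehand and does not decide the question. The markers did not move together: Cd14 was at 0.70 and Mpeg1 at 0.51, higher when adjusted over the list alone, the list was shifted upwards by camera (adjusted p = 0.0122, and adjusted p = 0.242 with an estimated correlation), and abundant Cd68, Fcer1g and Ly6c2, the last also expressed by T cells, were at -0.01, 0.23 and 0.08, with C1qb at -0.47. Female cells on PlGFCM replicate 2 stay open as a contribution: replicate 1 lay above all 4 arrays of the other groups for 5 of the 5 genes, but the genes were picked for high values in PlGFCM. A response to PlGF or to another component of the medium, in T cells or in the few myeloid cells present, may account for these values and was not tested, since medium and group coincide.

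The hypothesis that PlGFCM carried TGF-beta activity was drawn from Smad7, Skil, Pmepa1 and Ldlrad4, whose calls each need PlGFCM replicate 2, and tested on 21 other measured TGF-beta targets. Their mean log2 change against ConCM was 0.057, with 13 of 21 positive and none passing singly. Camera gave p = 0.00896 with the preset correlation, which met the rule written beforehand, and p = 0.313 with an estimated one. With the preset correlation 12 of 27 lists were shifted in this comparison, so meeting the rule does not single out TGF-beta, and the hypothesis stays open. For BMP activity, the rule written beforehand took a mean that was not positive as speaking against it. The 10 BMP targets had a mean of -0.056, with 2 of 10 positive, so that outcome was met. It was set aside because Hamp at 2.44 and Smad7, which passed and which BMP signalling can also induce, were left out of that list. The list therefore excludes nothing, and BMP activity stays open. Hamp was also higher in IL6_ConCM than in ConCM, though it did not pass there. Female cells on PlGFCM replicate 2 stay open as a contribution, since replicate 1 lay above both ConCM arrays for 4 of the 4 genes but genes that pass have groups that do not overlap, in 96 of 96 cases. TGF-beta or BMP made by the HEK-293 cells may differ between the media, the T cells may have released them, and PlGF itself may raise these genes, and these data hold no value that separates the 3.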
